A study of Mus musculus with 12 samples.

How the data were processed

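Expression was measured with a panel of 575 probes of the nCounter type (547 endogenous genes, 14 housekeeping genes, 6 positive and 8 negative controls) in 12 samples of RNA from paraffin-embedded mouse tumors. The samples made 4 groups of 3, with the letters A, B and C: MyC-CaP tumor cells alone, and MyC-CaP cells with WT, PIM1KO or TKO macrophages. The labels did not say whether the letters stood for separate animals, so the p-values measure the spread between these samples, which may be technical. All 12 samples came from 1 cartridge, and the lane order followed the groups (lanes 1 to 3 alone, 4 to 6 WT, 7 to 9 PIM1KO, 10 to 12 TKO), so lane and group could not be separated.

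The deposited values were used as a signal on a linear scale, never negative and with 2 decimals. The authors had scaled each sample to the 14 housekeeping genes: their geometric mean was 8032 in each of the 12 samples, control probes were left as whole counts, and values below 1 were listed as 1. The software and settings of this step are not given in the sources used here. Each sample's values over 1 and under 500 (327 to 378 per sample) lay within 0.05 counts of multiples of 1 step (0.86 to 1.115). The counts before scaling were therefore recovered by division and rounding, and higher values were not checked in this way. Recovered counts were used for depth, background, the positive control scaling, background subtraction and the spread between replicates, and not for a count model. A second table in the series held the same values in every cell. Background was the mean of the 8 negative controls plus 2 SD, times the sample's factor.

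Probe names were matched to current mouse symbols with RefSeq names of assembly GRCm38.p6: 549 by accession, 9 by symbol and 1 by synonym, with 2 left as in the file. Names in the text are those of the file, and 14 of them have another current symbol (Emr1 is Adgre1, Ccrl1 is Ackr4, Il28a is Ifnl2 and C1s is C1s1).

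Genes with a value of at least 20 in at least 3 of the 12 samples were tested (533 kept, 14 left out), on log2(value + 1). The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with all 12 samples in 1 fit with 8 residual degrees of freedom, 2-sided, Benjamini-Hochberg over the genes tested, and a threshold of adjusted p = 0.05. A total of 6 comparisons were made: WT vs alone, PIM1KO vs WT, TKO vs WT, TKO vs PIM1KO, PIM1KO vs alone and TKO vs alone, with a moderated F test of any difference between groups. Every adjusted p of a gene comes from limma and every n is 3 per group. Fold changes and log2 differences come from this fit, and group values are means ± SD. Where no sample of a group lay above background, a fold is given as a bound against background, and none unless all 3 samples of the other group lay above it. Where some samples of a group did, their number is given with the log2 difference.

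Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, against the other genes on the panel, with Benjamini-Hochberg over the lists of a comparison. Of 30 pathway and cell type lists, 20 kept at least 4 genes and were tested. The other 10 kept too few: cell cycle 0, oxidative stress response 0, PIM kinases 0, muscle, fat and skin around the tumor 0, hypoxia and glycolysis 1, extracellular matrix and remodelling 1, fibroblast 1, epithelial and prostate tumor cell 2, mast cell 2 and endothelial cell 3. A list of reference genes (17 in the table) served only for an alternative scaling. Camera asks whether a list moved more than the other genes of the panel; fry, run as an alternative, asks whether its genes moved at all. Per list, the genes that passed over all genes are counted, and beside them the genes that passed with the adjustment over that list alone.

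The groups, comparisons, tests, filter, gene lists, most alternative settings and the rule for naming genes were fixed before the data were examined. Genes named per comparison were the 12 highest and 12 lowest of those that passed, or, with fewer than 10 passing, also the 8 higher and 8 lower with the smallest unadjusted p. Members of the inflammasome and IL-1, macrophage, and alternatively activated lists that passed anywhere were named too, with up to 4 members of each list that passed. Further list members given as examples, and genes shown for sample TKO A, were chosen after the values were seen.

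The alternative settings fixed beforehand were a pseudocount of 0.5 or 10 in place of 1, no filter, a minimum value of 50, quantile normalization, scaling to the fixed reference genes, median centring, no variance trend, array weights, only the 2 groups compared, the letter as a block, leaving out each of the 12 samples, and for lists an estimated correlation and fry. Scaling of the recovered counts to the 6 positive controls, with no housekeeping step, and subtraction of the negative control mean were added after the values were seen. The positive controls are added to the reaction, so this scaling replaces the assumption of stable housekeeping genes by that of equal RNA input. The correlation of the PIM1KO and TKO changes was set against 1000 simulated sets of unchanged groups that share the WT samples. Other splits of the samples were counted (10 for 3 against 3, 100 drawn for the F test).

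The test was checked on simulated data: for TKO vs WT, in 20 simulated sets with 200 of 533 genes changed, it found 53.7% of changes of log2 0.5 and 88.2% of changes of log2 1, with the right sign in 100%, 2.82% false calls, and a shifted list in 20 of 20 sets. The simulated noise was independent between genes and alike in all samples, with rises and falls drawn at equal odds. The check therefore gives no rate of false calls for correlated genes or lists of them. Nor does it cover a sample that lies apart, such as TKO A, or changes mostly to 1 side. The other comparisons have the same n and were not simulated. Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9) was used for tables and figures. No sample was left out of the fit.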

Results

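The 12 samples were tumors grown from MyC-CaP cells, a mouse prostate cancer line driven by Myc, alone or with WT, PIM1KO or TKO macrophages (TKO, loss of PIM1, PIM2 and PIM3), with n = 3 per group and 2 weeks of growth. The sample labels and the series title call the added cells macrophages, the design text calls them MEFs and the source field reads cell culture. The group names here follow the sample labels. Recovered counts came to 1260467 (alone C) to 1516830 (alone A) per sample, and 40 (PIM1KO A) to 152 (alone A) of the 547 genes lay below background (28.1 to 48.0 signal units). Of these genes 533 were tested. Values are signal, as means ± SD, and changes are log2 differences from the limma fit of all 12 samples.

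Pim1, Pim2 and Pim3, the genes lost in the added cells, had no probe, so the knockout labels could not be checked in these data. Nlrp3, Arg1, Hmox1 and Cd68 had no probe either. The first principal component held 66.6% of the variance. Alone and WT samples lay on it between -8.98 and -5.36, PIM1KO between 0.026 and 1.16, TKO B and C at 11.6 and 13.1 and TKO A at 21.0. The median log2 difference of all tested genes was -0.043 for WT vs alone, 0.31 for PIM1KO vs WT, 0.48 for TKO vs WT, 0.18 for TKO vs PIM1KO, 0.28 for PIM1KO vs alone and 0.44 for TKO vs alone, with values scaled to the housekeeping genes. With positive control scaling the medians of PIM1KO vs WT and TKO vs WT were 0.026 and 0.23, and with median centring -0.16 and -0.33. A rise smaller than the gap between these medians and those of the housekeeping scaling therefore changed sign with the scaling. The F test of any difference between groups found 273 of 533 genes (250 without WT B to 326 without TKO A).

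No gene passed between tumors with WT macrophages and tumors of MyC-CaP cells alone. Of the macrophage markers, Emr1, the F4/80 antigen, read 772 ± 55.7 against 794 ± 89.9 (log2 -0.036). Csf1r, the receptor for the macrophage growth factor, read 906 ± 23.3 against 914 ± 85.6 (log2 -0.0084), and the differences of Itgam and Fcgr1 were log2 -0.042 and -0.025. None of the lowest p-values passed: Nfil3, a circadian and lymphoid transcription factor, read 2952 ± 81.6 against 4205 ± 213 (log2 -0.51, SE 0.11, adjusted p = 0.345). Cxcr4, the Cxcl12 receptor, read 363 ± 10.5 against 484 ± 16.7 (log2 -0.41, adjusted p = 0.345). Plau, Ccl11, Notch1 and Card9 were also on the lower side (log2 -0.32, -0.46, -0.40 and -0.31). On the higher side were Cd24a (log2 0.50, adjusted p = 0.697) and Bcap31 (0.16), all without passing. Pla2g2a (12.2 ± 3.7 against 23.1 ± 5.5) and Ltb4r2 (25.6 ± 2.3 against 16.7 ± 4.8) lay below background in all samples of both groups, so no fold is given. Il1b was 86.9 ± 15.7 against 188 ± 95.6 (log2 -1.0, adjusted p = 0.909), with alone B at 294.

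By limma 0 of 533 genes passed in WT vs alone, with 22 at unadjusted p under 0.05 (4 higher, 18 lower). Quantile normalization gave 1 gene, array weights 10, the fit of only these 2 groups 1 and the fit without TKO A 4, and the other settings 0. All 3 samples of one group lay above or below all 3 of the other in 101 of 533 genes, against 10% by chance.

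In the same comparison the neutrophil list (6 genes) moved up against the panel (camera, adjusted p = 0.000212, adjusted p = 0.36 with an estimated correlation, fry adjusted p = 0.895), with a median log2 of 0.56 and 0 of 6 genes passing. The same 0 was found when adjusted over the list alone. Its members include S100a8 and S100a9, the calprotectin subunits, at 461 ± 263 against 253 ± 72.0 and 432 ± 255 against 245 ± 59.1 (log2 0.76 and 0.69, both adjusted p = 0.909). Camp, a granule peptide, was another (39.6 ± 44.6 against 10.4 ± 1.9, adjusted p = 0.909), with 1 of 3 WT samples and 0 of 3 alone samples above background. WT A carried much of it, with S100a8 at 764 against 289 and 331 in WT B and C. Without WT A the adjusted p was 0.0236. The other 19 lists did not pass, with adjusted p between 0.308 and 0.895 and 0 genes passing in each. For the complement, checkpoint, apoptosis, B and plasma cell, MHC class I, MHC class II and type I interferon lists the camera direction was up while median and mean were below 0, since camera compares with the panel. The median of the dendritic cell list was -0.10 with a mean of 0.00023, and that of the T cell list 0.031 with a mean of -0.0093, both up by camera.

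**Figure D1:**
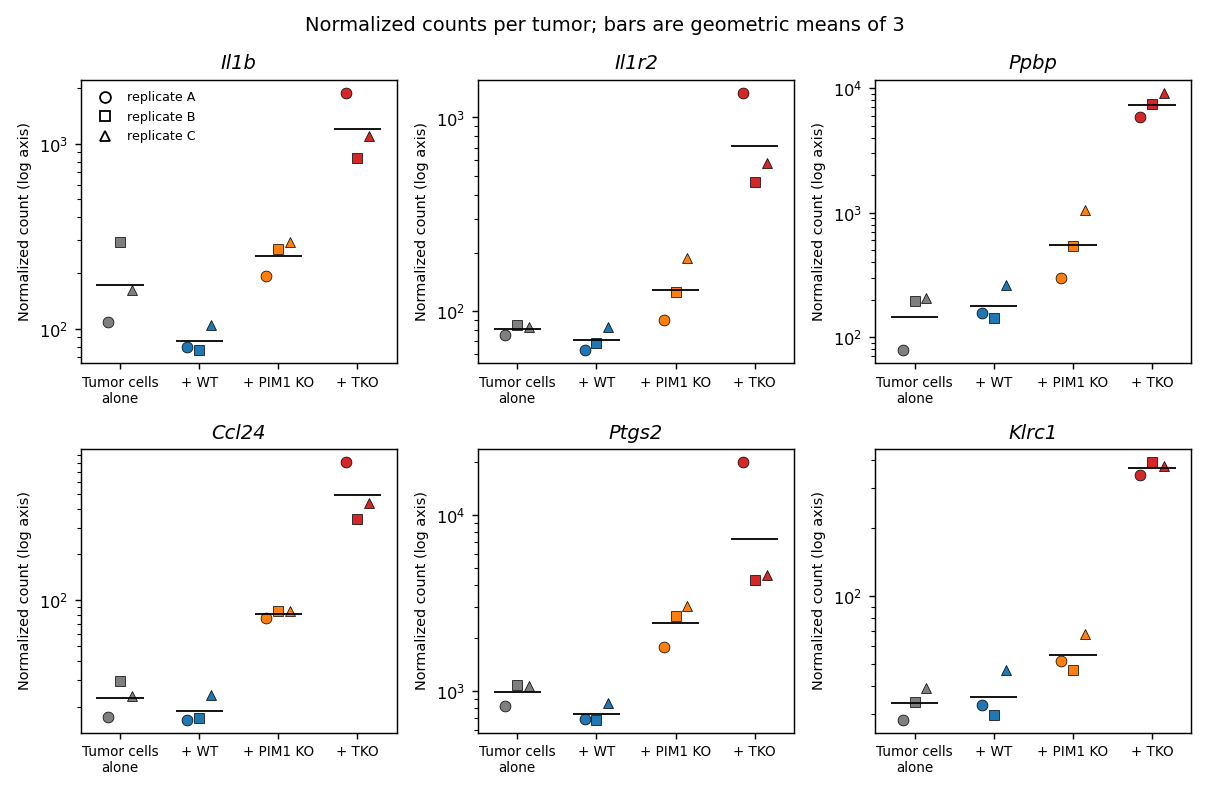
Signal of 6 genes in the 4 groups on a log axis, with a point per replicate and bars at the geometric mean of 3. The genes were chosen after the values were seen.

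In tumors with PIM1KO macrophages 99 genes were higher than in tumors with WT macrophages and 0 lower, and no list passed by camera. Ccl24, an eosinophil chemokine made by alternatively activated macrophages, rose from 19.1 ± 4.2, below background, to 82.1 ± 5.1 (at least 2.67-fold, adjusted p = 0.00135). Il33, an alarmin of the IL-1 family, rose from 117 ± 6.7 to 362 ± 51.5 (log2 1.62, SE 0.23, adjusted p = 0.00135). Serping1, the C1 inhibitor, rose from 1001 ± 73.5 to 2908 ± 594 (log2 1.52, SE 0.27, adjusted p = 0.00421). Cd209g, a C-type lectin gene, rose from 29.4 ± 4.9 to 81.5 ± 28.0 (log2 1.40, SE 0.24, adjusted p = 0.00355), with 1 of 3 WT samples above background. These 4 genes passed with the same sign in each of 25 alternative settings. Il18rap, the accessory chain of the IL-18 receptor (58.7 ± 9.4 to 255 ± 101, log2 2.03, adjusted p = 0.0072), passed in all but quantile normalization (log2 1.58).

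Further genes of PIM1KO vs WT passed by less. Ptgs2, the inducible cyclooxygenase, rose from 741 ± 94.2 to 2483 ± 643 (log2 1.71, adjusted p = 0.0331), and Il1b from 86.9 ± 15.7 to 253 ± 53.5 (log2 1.52, adjusted p = 0.0163). Ppbp, a neutrophil chemokine of platelets and myeloid cells, rose from 186 ± 64.4 to 630 ± 384 (log2 1.62, adjusted p = 0.0363), and Cd82, a tetraspanin, from 170 ± 26.4 to 456 ± 156 (log2 1.37, adjusted p = 0.0102). Ccrl1, a scavenging chemokine receptor, rose by log2 1.80 (adjusted p = 0.0331), Klra4, an NK receptor gene, by log2 1.43 (adjusted p = 0.0484). Il28a, an interferon lambda gene, lay below background in all samples of both groups (2.9 ± 1.0 and 18.5 ± 9.6, adjusted p = 0.0269, no fold given). With positive control scaling Ccl24 (adjusted p = 0.00782), Il18rap (log2 1.75), Il33 (1.34), Serping1 (1.24) and Cd209g (1.13) still passed. Il28a, Ccrl1, Ptgs2, Ppbp, Il1b, Klra4 and Cd82 did not, nor did any of the 5 genes that follow. All of these lost the call but kept their sign, while the median of all genes fell from 0.31 to 0.026. Of macrophage and IL-1 genes, Cd14, the LPS co-receptor, rose by log2 0.89 (adjusted p = 0.0111), Il1a by 0.88 (adjusted p = 0.0207, above background in 2 of 3 PIM1KO and 1 of 3 WT samples), and Il4ra by 0.65 (adjusted p = 0.015). Csf1r and Fcgr3 rose by 0.46 each (adjusted p = 0.00998 and 0.0331), with values of -0.013 and -0.012 under median centring. Emr1 (log2 0.054, adjusted p = 0.842), Fcgr1 (0.041), Casp1 (0.37, adjusted p = 0.102) and Il1r2 (0.85, adjusted p = 0.106) did not pass.

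Of the 17 named genes of PIM1KO vs WT that passed, 8 passed in every fit that left out 1 sample: Ccl24, Il33, Serping1, Cd209g, Il18rap, Cd14, Cd82 and Csf1r. Ccrl1 and Ptgs2 did not pass without any 1 of the WT or PIM1KO samples (highest adjusted p = 0.105 and 0.103). Nor did Ppbp and Il1b without WT A, WT B, PIM1KO B or PIM1KO C (0.118 and 0.0714), nor Il28a without WT B, WT C or PIM1KO A (0.0928). The same held for Il1a without WT A, WT B, PIM1KO A or PIM1KO B (0.0723), and for Fcgr3 without WT B, WT C, PIM1KO A, B or C (0.113). Il4ra was lost without WT B, PIM1KO A or PIM1KO B (0.0688), and Klra4 without alone A, alone C, WT A, WT B, PIM1KO B, PIM1KO C, TKO B or TKO C (0.15). For Ccrl1 and Ptgs2 the lowest adjusted p over the fits without 1 sample was 1.57e-05. All 12 samples share 1 estimate of the spread, and TKO A lay apart in both genes. Ccrl1 read 1799 in TKO A against 371 and 351 in TKO B and C, and Ptgs2 19946 against 4238 and 4520.

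By limma 99 genes were higher and 0 lower in PIM1KO vs WT (199 at unadjusted p under 0.05), of which 95 rose by more than the median of all genes and 20 by at least 2-fold. In all 99 the 3 PIM1KO samples lay above the 3 WT samples. Selection of genes by the same values favours this, here and in the other comparisons, so such counts add no support. Over all 533 genes the groups lay apart in 302, against 10% by chance. The split of the genes that passed depended on the scaling. It was 16 higher and 9 lower with quantile normalization, 11 and 93 with median centring, 11 and 2 with positive control scaling, and 85 and 0 after background subtraction. Of the 99 genes themselves 96, 83 and 97 kept their sign under the first 3 of these, with 0 reversed and passing in each. Array weights gave 247 higher and 12 lower, the fit of only these 2 groups 206 and 13, and the fit without TKO A 198 and 11. Without WT B the count was 44, without WT C 58, without PIM1KO A or PIM1KO B 54 each, and without WT A 68.

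No list passed by camera in PIM1KO vs WT (3 of 20 at unadjusted p under 0.05; 0 with an estimated correlation; 16 by fry). Type I interferon was closest, down against the panel (adjusted p = 0.075, and 0.0444 without WT B) with a median log2 of 0.11 and 0 of 10 genes passing. Genes that passed rose in complement (4 of 17, 7 adjusted over the list alone; C1s log2 1.20, C6 1.14) and TNF and NF-kB (6 of 18, 8 alone; Tnfrsf1b 0.81, Tnf 0.82). They rose in classically activated macrophage (6 of 15, 7 alone; Socs3 1.20, Cd86 0.68) and myeloid chemokines (5 of 17, 7 alone; Cxcl1 1.09, and Ccl7 0.47, just below 0 under median centring). The same was seen in checkpoint (3 of 11, 7 alone; Tnfrsf9 0.93, Tigit 0.73) and T cell (3 of 13, 4 alone; Cd3e 0.79, Cd4 0.69, Tcf7 0.69). Further counts were 3 of 8 in macrophage (5 alone), 3 of 10 in inflammasome and IL-1 (3 alone), 3 of 14 in interferon gamma (4 alone; Irf1 0.44, lower under median centring) and 2 of 11 in alternatively activated macrophage (5 alone). The remaining lists had 2 of 6 for neutrophil (3 alone; Cxcr2 0.93, Csf3r 0.68), 2 of 9 for B and plasma cell (Cd79b 0.59) and 2 of 9 for MHC class II (Ciita 0.76). There were 2 of 6 for TGF-beta (Smad3 0.46, Tgfbr2 0.36, both lower under median centring), 1 of 7 for NK cell (Klrd1 0.71), 1 of 7 for MHC class I (Psmb9 0.51), 1 of 12 for cytotoxic effectors (0 alone), 0 of 5 for dendritic cell and 0 of 7 for apoptosis. Of these genes Tigit and Cxcr2 lay above background in 2 of 3 PIM1KO and 1 of 3 WT samples, Cd3e in 1 of 3 of each, and Tnfrsf9 and Klrd1 in 2 of 3 WT samples.

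These list counts of PIM1KO vs WT depended on the scaling. With positive control scaling 2 genes passed in complement, 1 each in classically and alternatively activated macrophage, myeloid chemokines and inflammasome and IL-1, and 0 in every other list. With quantile normalization 2 rose in complement and 1 each in classically and alternatively activated macrophage, myeloid chemokines and TNF, with 1 fall each in apoptosis and NK cell. With median centring rises and falls were 2 and 3 in complement, 1 and 2 in classically activated, 1 and 1 in alternatively activated and in myeloid chemokines, 1 and 0 in inflammasome and IL-1, and 0 rose elsewhere. Without TKO A more genes rose: 12 in myeloid chemokines, 10 in TNF, 8 each in complement and classically activated, 7 each in checkpoint and interferon gamma, 6 each in alternatively activated and inflammasome and IL-1, and 5 each in macrophage and T cell.

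The highest list medians were log2 0.72 (neutrophil), 0.66 (complement), 0.65 (checkpoint), 0.61 (T cell), 0.58 (inflammasome and IL-1), 0.58 (B and plasma cell), 0.56 (classically activated), 0.51 (dendritic cell) and 0.48 (myeloid chemokines). Lower ones were 0.40 (macrophage), 0.39 (TNF and NF-kB), 0.36 (MHC class II), 0.34 (alternatively activated), 0.33 (cytotoxic), 0.23 (MHC class I), 0.23 (interferon gamma), 0.087 (NK cell), and near 0 for TGF-beta and apoptosis. Camera had the MHC class I, cytotoxic, NK cell and type I interferon lists down with medians above 0, and TGF-beta and apoptosis down with means of 0.099 and 0.0851. Median centring turned the medians of the macrophage (-0.072), alternatively activated (-0.13), TNF (-0.088), MHC class II (-0.12), cytotoxic (-0.14), MHC class I (-0.24), interferon gamma (-0.25), type I interferon (-0.37) and NK cell (-0.39) lists below 0. The inflammasome median stayed at 0.11 and that of complement at 0.18. Lists that name a cell type shared few genes. Of 8 macrophage genes 3 were in another list, of 6 neutrophil genes 1, of 7 NK cell genes 2, and of 13 T cell genes 0.

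**Figure D2:**
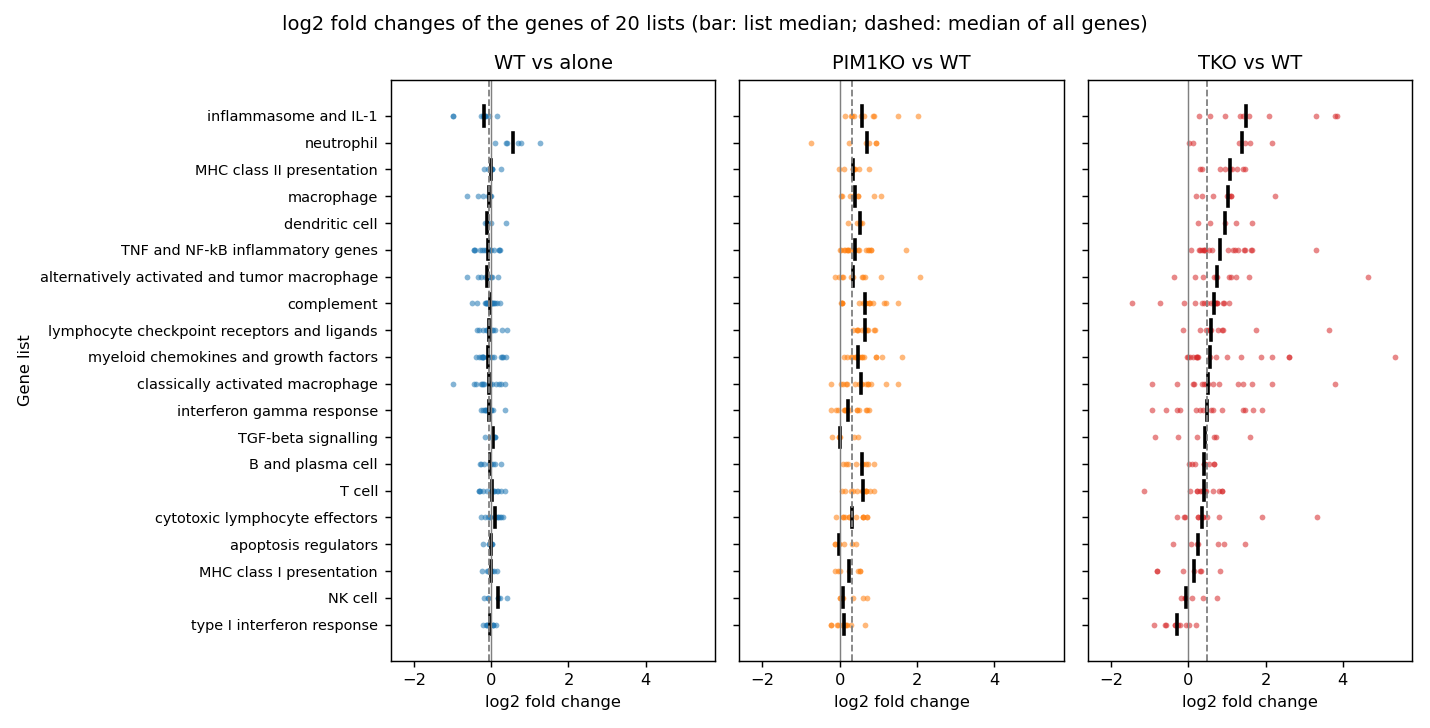
Log2 differences of the members of 20 gene lists in 3 comparisons, with bars at the list medians and a dashed line at the median of all genes. Under median centring several medians, such as those of the complement list in TKO vs WT and the macrophage list in PIM1KO vs WT, fall below 0.

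Tumors with TKO macrophages differed from those with WT macrophages in 281 genes. Ppbp rose from 186 ± 64.4 to 7507 ± 1661 (log2 5.36, SE 0.47, adjusted p = 5.13e-06, 41.0-fold), and Ccl24 from 19.1 ± 4.2, below background, to 528 ± 244 (at least 16.1-fold, adjusted p = 4.66e-07). Il1b, the inflammasome-processed cytokine, rose from 86.9 ± 15.7 to 1274 ± 546 (log2 3.79, SE 0.36, adjusted p = 9.19e-06, 13.8-fold). Il18rap rose from 58.7 ± 9.4 to 920 ± 485 (log2 3.84, adjusted p = 1.61e-05), and Il1r2, the decoy receptor for IL-1, from 71.4 ± 10.3 to 795 ± 476 (log2 3.31, adjusted p = 1.79e-05). Lif, a cytokine of the IL-6 family, rose from 137 ± 11.7 to 1494 ± 838 (log2 3.31, adjusted p = 1.07e-05). Ptgs2 rose from 741 ± 94.2 to 9568 ± 8989 (log2 3.30, adjusted p = 0.000141), and by log2 2.57 without TKO A. Cd82 (log2 4.13, adjusted p = 1.31e-06) and Cd44, the hyaluronan receptor (1268 ± 132 to 9762 ± 5461, log2 2.81, adjusted p = 2.09e-05), were also among the 12 highest. Without TKO A the rises of Lif and Cd44 were smaller as well (2.88 and 2.38), and that of Ppbp was larger (5.53).

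The other 3 of the 12 highest genes of TKO vs WT were lymphocyte receptor genes. Klra4 rose from 64.8 ± 29.7 to 1655 ± 671 (log2 4.67, SE 0.45, adjusted p = 9.19e-06), and Tigit, an inhibitory receptor of T and NK cells, from 24.8 ± 6.6 to 317 ± 71.1 (log2 3.63, SE 0.23, adjusted p = 4.66e-07), with 1 of 3 WT samples above background. Klrc1, which encodes NKG2A, rose from 36.6 ± 9.2 (2 of 3 above background) to 372 ± 24.3 (log2 3.34, SE 0.20, adjusted p = 4.18e-07). All 12 highest genes passed in each of 25 settings, with the 3 TKO samples above the 3 WT samples. Of 7 genes in the NK cell list 1 passed, Klra1 (adjusted p = 0.0318; below background in all samples of both groups, no fold given; 0 adjusted over the list alone). The list had a median log2 of -0.046 and a mean of 0.12 (camera down, adjusted p = 0.119), and without TKO A a median of 0.16 with 0 genes passing. Of the 7 members 4 lay above background, and the median was -0.85 under median centring. Cytotoxic effectors passed in 2 of 12 (median log2 0.37, -0.44 under median centring; Ifng 1.90). Prf1 (0.81, adjusted p = 0.0647), Gzmb (0.26), Eomes (0.25) and Gzma (39.2 in TKO, below background, against 42.6) did not pass. Samples above background in TKO and WT were 2 and 1 of 3 for Prf1, 2 and 3 for Gzmb and 1 and 2 for Eomes, and in WT 2 of 3 for Ifng and Tnfrsf9. T cell genes passed in 3 of 13 (Tcf7 0.86; median 0.40, -0.41 under median centring) and B and plasma cell genes in 1 of 9 (Tnfrsf13b 0.67, lower under median centring; median 0.41, -0.40 under median centring). Checkpoint genes passed in 4 of 11 (Tnfrsf9 1.74, Pdcd1 0.89, Cd274 0.87; median 0.58, -0.22 under median centring), and without TKO A in 6 (median 0.89).

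Members of the inflammasome and IL-1 list rose in TKO vs WT in 9 of 10 genes (median log2 1.49; camera adjusted p = 0.0938, adjusted p = 0.842 with an estimated correlation; fry adjusted p = 1.57e-05). Beside Il1b, Il18rap and Il1r2 these were Il1rl1, the IL-33 receptor (log2 2.10), Il1a (1.56, 1 of 3 WT samples above background), Il1rn, the IL-1 receptor antagonist (139 ± 23.7 to 372 ± 64.7, 1.42), Il1r1 (1.34), Il1rap (0.96) and Il18 (0.56). Without TKO A the rises were smaller for Il1b (3.46), Il18rap (3.44), Il1r2 (2.85), Il1rl1 (1.67), Il1r1 (0.93) and Il1rap (0.68), and larger for Il1rn (1.55), all still passing. The list then had 9 rises and a median of 1.51. Casp1, the protease that matures IL-1 beta, did not pass in the main fit (log2 0.28, adjusted p = 0.134, and -0.52 under median centring). With median centring 6 of the list's genes were higher and 1 lower (median 0.69), with quantile normalization also 6 and 1 (0.84), and with positive control scaling 8 and 0 (1.25). Il18 read -0.24 under median centring and -0.18 under quantile normalization, and did not pass without WT B, WT C or TKO B (highest adjusted p = 0.0935).

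Macrophage genes passed in 7 of 8 in TKO vs WT (median log2 1.03, 0.23 under median centring; camera adjusted p = 0.169). Cd14 rose from 229 ± 10.9 to 1123 ± 336 (log2 2.25, adjusted p = 5.13e-06), and Msr1, a scavenger receptor, from 394 ± 23.9 to 867 ± 192 (1.11). Fcgr3 rose from 395 ± 38.9 to 854 ± 69.5 (1.11), Itgam from 373 ± 14.2 to 758 ± 92.0 (1.02) and Csf1r from 906 ± 23.3 to 1425 ± 143 (0.65, -0.16 under median centring). Cd163 (24.6 ± 5.4 in WT, below background, and 57.0 ± 34.7 in TKO, adjusted p = 0.047, no fold given) and Fcgr1 (log2 0.35, adjusted p = 0.0321; -0.45 under median centring) passed by little. For Cd163 only TKO A, at 97.0, lay above background. Cd163 did not pass without any 1 of the alone or WT samples, PIM1KO B or TKO A (highest adjusted p = 0.145). Fcgr1 did not without any 1 of the WT samples, TKO B or TKO C (0.122). Emr1 did not pass (772 ± 55.7 to 913 ± 248, log2 0.20, adjusted p = 0.378; -0.60 under median centring), with TKO A at 627 and TKO B and C at 1070 and 1043. Without TKO A it passed (log2 0.45, adjusted p = 0.00299), as it did in TKO vs PIM1KO (0.40) and TKO vs alone (0.42). Il10 did not pass (log2 0.72, adjusted p = 0.054; 1 of 3 samples of each group above background). Of alternatively activated genes 8 of 11 rose (9 over the list alone; median 0.75, -0.057 under median centring), with Il4ra (1.58) and Ccl22 (1.24) beside Ccl24 and Msr1. Others were Tgfbi (0.75), Tgfb1 (0.67) and Stat6 (0.38), which read -0.057, -0.14 and -0.42 under median centring. Of classically activated genes 10 of 15 rose and 1 fell (median 0.51, -0.29 under median centring), with Socs3 (2.16), Cd80 (1.64) and Il6 (1.30) up and Cxcl10 down. The alternatively activated list shares 2 genes with the macrophage list, and the classically activated list 1.

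In the remaining lists of TKO vs WT most genes that passed rose with the housekeeping scaling, and the scaling decided the sign of several medians. TNF and NF-kB genes rose in 13 of 18 (median log2 0.82, 0.014 under median centring; Tnfrsf1b 1.63, Traf1 1.64, Bcl3 1.21, Relb 1.16), and MHC class II genes in 7 of 9 (median 1.07, 0.26 under median centring; Ciita 1.46, Cd74 1.43, H2-Ab1 1.25, H2-DMa 1.07). Dendritic cell genes rose in 4 of 5 (0.95, 0.14; Itgax 1.64, Batf3 0.95) and neutrophil genes in 4 of 6 (1.39, 0.58; Cxcr2 2.17, S100a9 1.60, Csf3r 1.46, S100a8 1.32). Myeloid chemokines and growth factors rose in 9 of 17 (0.57, -0.23 under median centring; Cxcl1 2.62, Csf2 1.89). For Cxcr2 and Csf2 1 of 3 WT samples lay above background. Interferon gamma genes rose in 8 and fell in 1 of 14 (0.49, -0.32; Socs1 1.69, Irf1 0.59), and complement genes rose in 7 and fell in 1 of 17 (0.66, -0.15; C1s 0.92, Cfp 0.72, C1qa 0.40). Complement had a mean of 0.40 and camera down (adjusted p = 0.581), and without TKO A 12 of its genes rose. The rises of Irf1, Cfp, C1qa and Bid were small enough to turn to falls under median centring. TGF-beta genes rose in 4 and fell in 1 of 6 (0.45, -0.36 under median centring; Smad3 1.60). Apoptosis genes rose in 3 and fell in 1 of 7 (0.26, -0.54; Casp8 0.93, Bid 0.78, Bcl2 -0.41). Camera had the interferon gamma, TGF-beta, apoptosis, T cell, B and plasma cell and cytotoxic lists down with medians above 0, as for complement. None of the lists of this paragraph passed by camera, and each of those counted here had a fry adjusted p of 0.00758 or less.

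The counts of rises and falls in TKO vs WT changed with the scaling as well. With quantile normalization they were 0 and 3 in complement, 4 and 5 in interferon gamma, 7 and 5 in myeloid chemokines, 9 and 4 in TNF, 2 and 3 in TGF-beta, 1 and 3 in apoptosis, and 5 and 2 in classically activated. They were 4 and 0 in macrophage, 4 and 2 in alternatively activated, 5 and 0 in MHC class II, 3 and 0 in neutrophil and 1 and 0 in dendritic cell. In T cell 0 rose and 2 fell, in NK cell 0 and 3, in MHC class I 0 and 5, in cytotoxic effectors 2 and 3, in checkpoint 2 and 1 and in B and plasma cell 0 and 1. With median centring complement had 0 and 5, interferon gamma 3 and 8, myeloid chemokines 6 and 8, TNF 5 and 4, macrophage 2 and 2 and MHC class II 3 and 1. With positive control scaling these 6 lists had 4 and 1, 7 and 3, 7 and 0, 10 and 0, 5 and 0, and 7 and 0. Without TKO A myeloid chemokines had 13 rises.

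Pigr, C7 and B2m were among the 18 genes that were lower in TKO vs WT. Pigr, the transporter of polymeric immunoglobulin, fell from 343 ± 57.3 to 108 ± 58.2 (log2 -1.84, SE 0.39, adjusted p = 0.00185), and C7, a terminal complement component, from 211 ± 12 to 84.1 ± 39.3 (log2 -1.45, SE 0.36, adjusted p = 0.00499). Il18r1, a chain of the IL-18 receptor, fell from 5732 ± 253 to 2649 ± 1408 (log2 -1.31, adjusted p = 0.00981) and Il16 from 1168 ± 35.4 to 568 ± 159 (log2 -1.08, adjusted p = 0.000453). Stat5a (-1.10), Cxcl10, a chemokine induced by interferon (-0.94, adjusted p = 0.0138), Tgfb3 (-0.87) and H2-K1 (-0.81, adjusted p = 0.0474) were lower too, as were B2m, the light chain of MHC class I (181400 ± 7703 to 110900 ± 44260, log2 -0.81, adjusted p = 0.0159), Il15ra (-0.69) and Stat5b (-0.68). For Pigr, C7 and Cxcl10 2 of 3 TKO samples lay above background. Sample TKO A made these falls larger. Without it they were -1.26 for Pigr, -0.97 for C7, -0.74 for Il18r1, -0.84 for Il16, -0.61 for Stat5a, -0.51 for Cxcl10, -0.51 for Tgfb3, -0.31 for H2-K1, -0.41 for B2m, -0.40 for Il15ra and -0.44 for Stat5b, all still passing. H2-K1 did not pass without any 1 of the alone, WT or PIM1KO samples (highest adjusted p = 0.106).

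The type I interferon list was lower against the panel in TKO vs WT (camera, adjusted p = 4.3e-05, adjusted p = 0.842 with an estimated correlation; fry adjusted p = 0.339). Its median log2 was -0.30, and 1 of 10 genes passed, Ifi35 (2749 ± 42.0 to 1880 ± 466, log2 -0.58, adjusted p = 0.00664). Bst2, which encodes tetherin (-0.88, adjusted p = 0.0687), and Ddx58, which encodes RIG-I (-0.27, adjusted p = 0.236), did not pass. Without TKO A Bst2 passed with a smaller difference (log2 -0.28). Without TKO A the list did not pass (adjusted p = 0.0712) and its median was 0.055, with 1 gene higher and 2 lower. The scalings kept it lower, with adjusted p = 0.0304 and a median of -0.94 for quantile normalization, 0.0416 and -1.10 for median centring, and 0.000657 and -0.55 for positive control scaling. Genes lower under these 3 were 9, 9 and 4 of 10, in place of 1. Median centring and positive control scaling move all genes of a sample together, so they say little on a drop against the panel. All 3 also keep TKO A: against the alone and WT samples the list median was -0.97 in TKO A and 0.036 in TKO B and C. MHC class I genes rose in 1 (Psmb10 0.33, lower under median centring) and fell in 2 of 7 (0 and 0 over the list alone). Their list (median 0.15, mean -0.021, camera down with adjusted p = 0.0938) had a median of -0.65 under median centring, and without TKO A one of 0.31 with 2 rises and 2 falls.

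**Figure D3:**
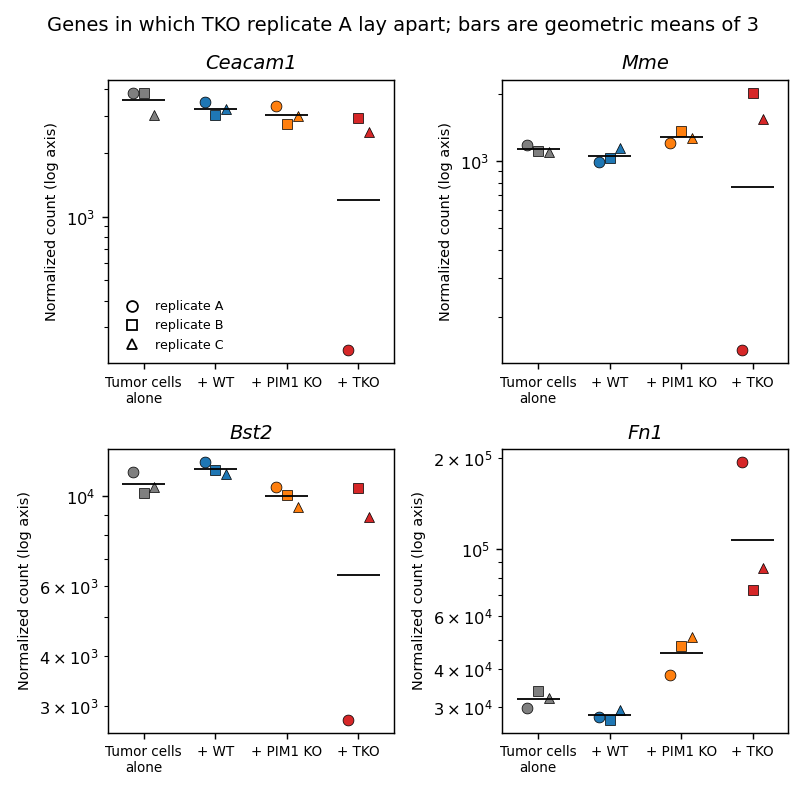
Signal of Ceacam1, Mme, Bst2 and Fn1 in each of the 12 samples, with TKO A apart from TKO B and C. The genes were chosen after the values were seen.

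By limma 263 genes were higher and 18 lower in TKO vs WT (313 at unadjusted p under 0.05), with 233 above and 48 below the median of all genes, and 113 and 6 by at least 2-fold. In 277 of the 281 genes the groups lay apart, and in 344 of all 533. Of the 43 named genes that passed, 38 passed in every fit without 1 sample and 23 with the same sign in every setting. The split was 100 higher and 137 lower with quantile normalization (18 of the 281 reversed and passing), 77 and 188 with median centring (39 reversed and passing), 173 and 41 with positive control scaling, and 235 and 20 after background subtraction. The count ran from 250 without WT C to 311 without TKO A, and 10 of the 281 genes lay below background in both groups.

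The step from PIM1KO to TKO was tested directly, and the genes highest in TKO passed here as well. Ppbp rose from 630 ± 384 to 7507 ± 1661 (log2 3.74, adjusted p = 0.000231), Klra4 by 3.24 and Tigit by 2.90 (adjusted p = 1.45e-05, 2 of 3 PIM1KO samples above background). Cd82 rose by 2.76, Klrc1 from 55.8 ± 11 to 372 ± 24.3 (2.73, adjusted p = 8.97e-06) and Ccl24 by 2.58 (adjusted p = 0.000132). Further rises were Il1r2 by 2.46, Cd44 by 2.31, Il1b from 253 ± 53.5 to 1274 ± 546 (2.27, adjusted p = 0.000929) and Lif by 2.23. Sigirr, an inhibitory receptor of the IL-1 family, rose from 124 ± 9.9 to 581 ± 120 (2.20, adjusted p = 8.97e-06) and Cxcr3, the receptor of Cxcl10, by 2.08. Among the 12 lowest were 2 of the genes that were raised in PIM1KO. Il33 fell from 362 ± 51.5 to 211 ± 72.0 (log2 -0.83, adjusted p = 0.0149) and Cd209g from 81.5 ± 28.0 to 42.1 ± 3.0 (-0.88, adjusted p = 0.013, 1 of 3 TKO samples above background). C7 (-1.94, adjusted p = 0.00182), Pigr (-1.32, adjusted p = 0.0186), Cxcl10 (-1.12, adjusted p = 0.00799) and H2-K1 (-1.04) were lower, and Cxcl13 passed on the lower side (51.0 ± 19.3, 2 of 3 above background, and 23.6 ± 7.0, below it, no fold given). Also lower were Ccl8 (1080 ± 294 to 573 ± 231, log2 -0.98, adjusted p = 0.0241), Stat5a (-0.91), B2m (-0.81), Il16 (-0.76) and Il21r (-0.69). For C7, Pigr, Cxcl10 and Il21r 2 of 3 TKO samples lay above background. Without TKO A these falls too were smaller: Il33 -0.51, C7 -1.47, Pigr -0.74, Cxcl10 -0.70, H2-K1 -0.54, Ccl8 -0.58, Stat5a -0.42, B2m -0.41, Il16 -0.52 and Il21r -0.45, all but Il21r still passing.

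By limma 192 genes were higher and 23 lower in TKO vs PIM1KO, 46 and 5 of them by at least 2-fold (246 at unadjusted p under 0.05). The groups lay apart in 214 of the 215, and in 259 of all 533. The split was 70 and 94 with quantile normalization, 60 and 102 with median centring, 180 and 20 with positive control scaling and 125 and 4 in the fit of only these 2 groups. The count ran from 171 to 233 without 1 sample. Of 38 named genes that passed, 28 passed in each such fit. Il33 and Pigr did not pass without PIM1KO A (adjusted p = 0.055 and 0.0511), nor B2m, H2-K1 and Stat5a without any 1 PIM1KO sample (highest 0.0572, 0.0562 and 0.085). Ccl8 was lost without PIM1KO A or B (0.0903), Ccl22 without PIM1KO C, TKO B or TKO C (0.112) and Il1a without PIM1KO C, TKO A or TKO B (0.106). Cxcl13 was lost without alone A, alone C, WT B, WT C, PIM1KO A, PIM1KO B, TKO B or TKO C (0.146), and Il21r without TKO A, TKO C or any 1 of the WT or PIM1KO samples (0.124).

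The type I interferon list was again lower against the panel in TKO vs PIM1KO (camera, adjusted p = 0.00435, adjusted p = 0.527 with an estimated correlation; fry adjusted p = 0.234), with 0 of 10 genes passing and a median log2 of -0.40. Without TKO A it did not pass (adjusted p = 0.123) and its median was -0.013, nor did it pass with array weights (0.0555). With quantile normalization 5 of the 10 genes were lower and with median centring 6. The other 19 lists did not pass by camera, which had the classically activated list down with a median of 0.31. It also had the T cell list down with 0.0089 (mean -0.18), and the cytotoxic and checkpoint lists down with medians of -0.031 and -0.10 and means of 0.28 and 0.30. Without TKO A the medians of these last 3 lists changed sign (-0.014, 0.087 and 0.042). Genes rose in inflammasome and IL-1 (7 of 10), MHC class II (7 of 9), TNF and NF-kB (12 of 18, 13 over the list alone), macrophage (4 of 8, 5 alone) and alternatively activated macrophage (7 of 11). In T cell and NK cell 0 passed either way. Rises and falls were 6 and 1 in classically activated macrophage (8 and 1 alone), 8 and 2 in myeloid chemokines, 3 and 1 in complement, and 1 and 2 in MHC class I. They were 6 and 1 in interferon gamma (7 and 1 alone), 4 and 1 in checkpoint, 2 and 1 in cytotoxic effectors, and 3 and 1 in TGF-beta (4 and 1 alone). Neutrophil and dendritic cell lists had 2 rises each, apoptosis 3, and B and plasma cell 1 (0 alone).

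With quantile normalization rises and falls in TKO vs PIM1KO were 2 and 1 in TNF, 0 and 6 in complement, 5 and 6 in myeloid chemokines, 2 and 0 in macrophage, 3 and 0 in alternatively activated, 5 and 1 in inflammasome and IL-1, 4 and 0 in MHC class II, 4 and 2 in interferon gamma, 0 and 4 in MHC class I and 0 and 3 in T cell. With median centring the first 5 of these lists had 2 and 2, 0 and 5, 5 and 5, 2 and 0, and 2 and 0. With positive control scaling they had 10 and 0, 3 and 1, 8 and 2, 4 and 0, and 7 and 0. Without TKO A macrophage genes rose in 6 and interferon gamma genes in 9.

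Compared with tumor cells alone, 53 genes were higher in PIM1KO tumors, and no list passed by camera. Il33 rose from 112 ± 14.7 to 362 ± 51.5 (log2 1.68, adjusted p = 0.00639) and passed in each of 25 settings. Ccl24 rose from 23.5 ± 6.2, below background, to 82.1 ± 5.1 (at least 2.35-fold, adjusted p = 0.00669), S100a9 from 245 ± 59.1 to 758 ± 134 (log2 1.64), S100a8 from 253 ± 72.0 to 709 ± 85.0 (1.52) and Serping1 by 1.37. Ppbp (1.92), C6 (1.30), Cd209g (1.15, 2 of 3 alone samples above background), C1s (1.06) and Tlr5 (0.98) also passed. So did Cxcr2, the neutrophil chemokine receptor (19.2 ± 0.60, below background, and 49.9 ± 8.6, 2 of 3 above it, no fold given), and Il28a, below background in both groups with no fold given. Without alone A the calls of Cd209g (adjusted p = 0.0615), Ppbp, S100a8, S100a9 and Csf1r ended (highest adjusted p over the fits without 1 sample 0.102, 0.113, 0.0737 and 0.0728). Il28a was lost without alone B, alone C, PIM1KO A or PIM1KO C (highest adjusted p = 0.0998), Ppbp also without PIM1KO B or C, S100a8 without alone C or any 1 PIM1KO sample, and S100a9 without alone C or PIM1KO C. Csf1r was lost also without alone C, PIM1KO A or PIM1KO B, and Tlr5 without alone C (0.0515).

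In PIM1KO vs alone 53 genes were higher and 0 lower by limma, 11 of them by at least 2-fold (165 at unadjusted p under 0.05). The groups lay apart in all 53, and in 229 of all 533. The split was 3 and 2 with quantile normalization, 12 and 50 with median centring, and 2 and 0 with positive control scaling. The count was 30 without alone A, 28 without alone C, 32 without PIM1KO A and 167 without TKO A. No list passed by camera (neutrophil up and type I interferon down, both adjusted p = 0.0572; 0 with an estimated correlation, 16 by fry), while 4 of 6 neutrophil genes (median log2 1.05) and 4 of 17 complement genes (7 over the list alone) passed on their own. With quantile normalization and with positive control scaling 0 genes passed in both of these lists. With median centring 4 neutrophil genes (median 0.70) and 3 complement genes still rose, and after background subtraction 4 of 4 and 4 of 15. Without TKO A complement had 8.

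TKO tumors differed from tumor cells alone in 280 genes. Ppbp rose from 159 ± 70.3 to 7507 ± 1661 (log2 5.65, adjusted p = 5.24e-06), and Klra4 by 4.57. Ccl24 rose by at least 14.2-fold and Tigit by at least 8.95-fold, both below background in all 3 alone samples. Rises followed for Klrc1 by log2 3.43 (2 of 3 alone samples above background), Cd82 by 3.38, Il1r2 by 3.12, Cxcl3 by 2.90 (1 of 3), Ptgs2 by 2.89, Lif by 2.88, Sigirr by 2.86, Il18rap by 2.85 and Il1b by 2.79. Lower genes were C7 (-1.57), Pigr (-1.57), Il18r1 (-1.27), Il16 (-1.23), Cxcl10 (-1.19), Stat5a (-1.15), Tgfb3 (-1.04), Stat5b (-0.74), B2m (-0.74), Cxcl11 (-0.68) and Bcl2 (-0.61), with 2 of 3 TKO samples above background for C7, Pigr, Cxcl10 and Cxcl11. Without TKO A the rise of Ptgs2 was 2.16, and the lower genes read C7 -1.10, Pigr -0.98, Il18r1 -0.69, Il16 -0.99, Cxcl10 -0.77, Stat5a -0.66, Tgfb3 -0.68, Stat5b -0.49, B2m -0.34, Cxcl11 -0.36 and Bcl2 -0.41, all but Cxcl11 still passing. Of 44 named genes that passed, 38 did so in every fit without 1 sample. B2m did not without any 1 of the alone samples (highest adjusted p = 0.064), Cxcl11 without alone A, alone C or TKO A (0.11), and Il10 without alone C or TKO A (0.0867). The same held for Fcgr1 without any 1 sample other than alone B and TKO A (0.167), and Il18 without any 1 of the alone samples, WT C, TKO A or TKO B (0.117).

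By limma 262 genes were higher and 18 lower in TKO vs alone, 103 and 7 of them by at least 2-fold (304 at unadjusted p under 0.05). The groups lay apart in 273 of the 280, and in 318 of all 533. The split was 87 and 137 with quantile normalization, 81 and 156 with median centring, and 183 and 36 with positive control scaling. Type I interferon was the list that passed, down (camera, adjusted p = 2.63e-05, adjusted p = 0.799 with an estimated correlation; median log2 -0.41, 1 of 10 genes lower). Without TKO A that median was 0.016. With quantile normalization 8 of its genes were lower, with median centring 9 and with positive control scaling 5. Inflammasome and IL-1 genes rose in 9 of 10 and macrophage genes in 6 of 8, and with quantile normalization in 6 (1 fell) and 3.

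**Figure D4:**
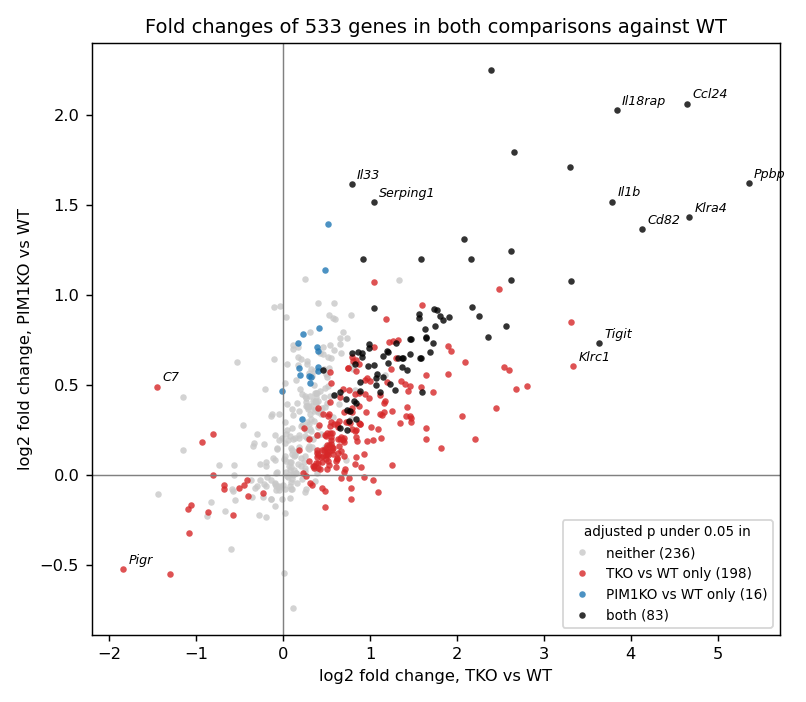
Log2 differences of 533 genes in PIM1KO vs WT against TKO vs WT, marked by the comparison in which they passed. The 3 WT samples are shared by the axes, and the position of 0 moves with the scaling.

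Of the 99 genes higher in PIM1KO vs WT, 83 were also higher in TKO vs WT, among them Ccl24, Ppbp, Il1b, Ptgs2 and Cd82. Calls independent of each other would share 48.8 genes, but the 2 comparisons share the WT samples and the scaling. The count expected from that sharing was not computed, so the 83 cannot be weighed against it. Of the 99, 79 changed more in TKO. Directly tested, 64 of the 99 were higher in TKO than in PIM1KO, 30 did not pass and 5 were lower (Bcl6, C4a, Ccl7, Cd209g and Il33). The log2 differences of the 533 genes had r = 0.665 (rho = 0.602). This stood against a mean of r = 0.503 and a highest value of 0.721 in 1000 simulated sets of unchanged groups that share the WT samples. The covariance was 0.210 against 0.0311 in those sets. PIM1KO vs WT against TKO vs alone, which share no sample, gave r = 0.581, a comparison chosen after the values were seen.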

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

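The tests in this part were chosen after the values were seen, apart from the fit without TKO A, which was planned as 1 of 12 fits that each left out 1 sample. The 14 housekeeping genes, which scale the samples and were outside the comparisons, were tested in the same way with limma. In TKO vs WT 6 of the 14 passed with the adjustment over these 14: Alas1 (log2 -0.63, adjusted p = 8.45e-05), G6pdx (-0.62), Sdha (-0.35), Gapdh (0.25, adjusted p = 0.0173), Tbp (0.37) and Tubb5 (1.19, adjusted p = 0.00144; mean 2472 against 1047). The scaling holds their geometric mean at 1 value, so only their unequal change can be read. With median centring Gapdh and Tbp turned to -0.55 and -0.43, and Alas1, G6pdx and Sdha read -1.43, -1.42 and -1.15. Rpl19 and Polr2a, at 0.017 and 0.013 with the housekeeping scaling, read -0.79 each, and of the 14 only Tubb5 stayed above 0 (0.38). Median centring thus lowered the housekeeping genes as a set, so a fall under it need not be a fall against them. With positive control scaling Gapdh read 0.0024, Alas1 -0.87, G6pdx -0.87, Sdha -0.60, Tbp 0.13 and Tubb5 0.94. In PIM1KO vs WT and in WT vs alone 0 of the 14 passed.

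Nearly all calls in PIM1KO vs WT and TKO vs WT were higher, which may come from the scaling to the housekeeping genes. With positive control scaling the median log2 difference of PIM1KO vs WT fell from 0.31 to 0.0263 and 13 genes passed in place of 99. For most of these 99 genes the scaling thus stays a candidate cause of the call, while Ccl24, Il33, Serping1, Cd209g and Il18rap still passed. Of the 99, 97 kept their sign under it and 83 under median centring. These genes were selected as higher with the housekeeping scaling, which favours a kept sign. Among all genes that passed under median centring, 11 were higher and 93 lower, so the direction over the panel depended on the scaling. For TKO vs WT positive control scaling took the median from 0.48 to 0.234 and 214 genes passed, 173 higher and 41 lower in place of 263 and 18. The median above 0 argues against the housekeeping scaling as the whole cause there, and a part in it stays open. Background at low counts was argued against in both: with the negative control mean subtracted the medians were 0.291 (85 genes) and 0.501 (255 genes). Positive control scaling assumes equal RNA input, which was not tested, and a real shift of many immune genes stays open.

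TKO A lay far from TKO B and C: its chi-square per degree of freedom was 277 and 233 against them, and 2.04 to 13.3 in the other pairs within groups. A label from another group was argued against, since TKO A lay above all 6 WT and PIM1KO samples in 85.5% of the 110 genes over 2-fold higher in TKO B and C, and so were fewer counts, with 1465896 recovered in TKO A and 1346848 as the highest of TKO B and C. Ceacam1 read 233 against 2500 to 3851 in the other 11 samples, Mme 142 against 986 to 2019, and Fn1 193323 against at most 86120. A larger share of the cells that mark TKO B and C might explain the 117 genes over 2-fold higher in TKO A than in alone and WT samples, 0 of which lay on the other side in TKO B and C, but of the 32 lower genes 11 lay on the other side, a criterion set with the values known. Other tissue in this section, or another tumor clone, was not tested.

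Klra4, Klrc1 and Tigit rose in TKO with no like rise of the NK cell list. More NK cells alone would raise the members by about as much as Klrc1 (log2 3.34), and the list median was -0.046 (0.161 without TKO A), with Il2rb at 271 against 267, Klrk1 at 77.9 against 80.3 and Xcl1 at 57.6 against 61.0, so this explanation was argued against, with 3 of 7 members near background. Whether transcripts of the other Klra genes on the panel add to the Klra4 signal cannot be told: the highest of them, Klra8, read 164.7 in TKO against 1655 for Klra4, but probes differ in efficiency. Klra8 itself rose (48.9 ± 2.1 to 165 ± 19.7, adjusted p = 1.92e-06 by limma), and Klrc2 read higher too (44.1 ± 1.5 to 78.0 ± 14.7). Nearer to background, Klra6 and Klrd1 read 52.8 and 45.8 in TKO against 40.4 and 34.8 in WT, and Klra5 24.0 against 27.2. Expression in another cell type, related genes with no probe, and the identity of the added cells (MEFs or macrophages) stay open and were not tested.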

How the results depend on the processing

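The positive control scaling and the background subtraction were chosen only after the values were seen, and the other settings were planned; where a value moved, the cause was not tested. The planned table of the series matrix holds identical values, moves nothing and was not run. Of 6548 alternatives to 263 values of named genes, 6054 stayed the same, 338 were weaker, 127 stronger and 29 reversed. A change of sign was counted as reversed only where the gene passed in either fit, and as the same otherwise.

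The genes passing in WT vs alone were 0, and 1 with quantile normalization, 10 with array weights, 1 with only the 2 groups compared and 0 to 4 without 1 sample (4 without TKO A). For PIM1KO vs WT the 99 became 25 with quantile normalization, 259 with array weights, 13 with positive control scaling, 219 with only the 2 groups compared, and 44 (without WT B) to 209 (without TKO A). TKO vs WT had 281, with 250 to 311 without 1 sample. TKO vs PIM1KO had 215, with 129 for only the 2 groups compared and 171 to 233 without 1 sample. PIM1KO vs alone had 53, with 5 for quantile normalization, 194 for array weights, 2 for positive control scaling, 108 for only the 2 groups compared, and 28 (without alone C) to 167 (without TKO A). TKO vs alone had 280 and 244 to 306, and the F test 273 and 250 to 326.

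Lists passing in WT vs alone were 1, with 0 for the estimated correlation, 0 for fry and 1 to 1 without 1 sample. PIM1KO vs WT had 0, with 16 for fry and 0 to 1 (without WT B) without 1 sample. TKO vs WT had 1, with 2 each for quantile normalization, median centring and positive control scaling, 0 for the estimated correlation, 17 for fry and 0 (without TKO A) to 1. TKO vs PIM1KO had 1, with 3 each for a minimum value of 50, quantile normalization and median centring, 2 for only the 2 groups compared, 0 for array weights and for the estimated correlation, 12 for fry and 0 (without TKO A) to 2 (without TKO C).

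The correlation of log2 differences, 0.665, was 0.724 with a minimum value of 50, 0.709 with array weights, 0.710 with background subtracted and 0.547 (without PIM1KO C) to 0.732 (without PIM1KO A) without 1 sample.

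The letters A, B and C did not pair the samples (18 pairs of the same letter, r from -0.176 to 0.332; 4 of 12 samples closest to their own letter). With the letter as a replicate block the genes passing were 0 in WT vs alone, 79 in PIM1KO vs WT, 279 in TKO vs WT, 203 in TKO vs PIM1KO, 45 in PIM1KO vs alone, 272 in TKO vs alone and 270 by the F test, the lists 1, 0, 1 and 1 in the first 4, and r = 0.665.

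Under positive control scaling 97 of the 99 genes of PIM1KO vs WT and 278 of the 281 of TKO vs WT kept their sign, with 0 reversed and passing. Reversed signs of named genes, counted only where the gene passed in either fit, came from 2 scalings. Under median centring these were Csf1r (-0.013), Fcgr1 (-0.43), Fcgr3 (-0.012) and Stat6 (-0.40) in PIM1KO vs WT, Casp1 (-0.52), Csf1r (-0.16), Emr1 (-0.60), Fcgr1 (-0.45), Il18 (-0.24), Stat6 (-0.42), Tgfb1 (-0.14) and Tgfbi (-0.057) in TKO vs WT, Stat6 (-0.017) in TKO vs PIM1KO, Fcgr1 (-0.33) in PIM1KO vs alone, and Casp1 (-0.66), Csf1r (-0.041), Emr1 (-0.51), Fcgr1 (-0.35), Il18 (-0.18) and Stat6 (-0.30) in TKO vs alone. Under quantile normalization they were Casp1 (-0.50), Fcgr1 (-0.29), Il18 (-0.18) and Stat6 (-0.29) in TKO vs WT, Stat6 (-0.082) in TKO vs PIM1KO, and Casp1 (-0.74), Fcgr1 (-0.23), Il18 (-0.15) and Stat6 (-0.25) in TKO vs alone.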

Other observations

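The tests in this part were chosen after the values were seen, apart from the counts of other splits, which were required beforehand for each count of genes. Il33, the IL-1 family alarmin, and its receptor gene Il1rl1 moved apart from PIM1KO to TKO, with log2 differences of -0.83 (adjusted p = 0.0149) and 1.47 (adjusted p = 0.00757). Without TKO A these were -0.51 and 1.04, and without PIM1KO A the fall of Il33 did not pass (adjusted p = 0.055). Over all fits without 1 sample this fall of Il33 ran from log2 -1.02 to -0.51. In WT, PIM1KO and TKO Il33 read 117 ± 6.7, 362 ± 51.5 and 211 ± 72.0, and Il1rl1 77.8 ± 10.2, 120 ± 7.3 and 367 ± 204. Against WT both means were thus higher in TKO with the housekeeping scaling. For Il33 TKO A, at 129, lay near the WT samples (109 to 122), with TKO B and C at 264 and 241. Median centring took the median of all genes in TKO vs WT from 0.48 to -0.33, and the sign of Il33 there is not given. Cd209g had the same shape as Il33 (29.4 ± 4.9, 81.5 ± 28.0 and 42.1 ± 3.0 in WT, PIM1KO and TKO, with 1, 3 and 1 of 3 samples above background).

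The PIM1KO changes may be the TKO changes at a smaller size. Of the 99 genes higher in PIM1KO vs WT, 5 were lower in TKO than in PIM1KO (5.05%), just over the bound of 5% set for this hypothesis, and the correlation with no shared sample was r = 0.581, above its bound of 0.3. An allowance for counting error was added after this result was seen, so the test decides nothing for the set, and both bounds were written with the values known. The 5 genes (Bcl6, C4a, Ccl7, Cd209g and Il33) were selected as high in the same PIM1KO samples that TKO was then compared with. That selection favours a fall in TKO, so as single genes they do not decide the question either. Without PIM1KO A the fall of Il33 lost its call and kept its sign. The genes up in both were 83, and the scaling common to both comparisons was not removed from this count.

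Splits of 3 against 3 samples number 10, too few for a share under 0.05. The real splits gave 0 genes in WT vs alone (as many as in 10 of 10 splits, highest other 0), 99 in PIM1KO vs WT, 281 in TKO vs WT, 215 in TKO vs PIM1KO, 53 in PIM1KO vs alone and 280 in TKO vs alone, each as many in 1 of 10 splits, with 0 as the highest of the others. For the F test of any group 1 of 100 splits, the real one, gave as many as 273 genes, and the highest other gave 201. A chance split of these 12 samples was thus unlikely there. A chance difference between tumors was not excluded, since the letters may not stand for separate animals. The lane order followed the groups, so a lane effect could not be told from a group effect.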
